A study of Arabidopsis thaliana with 4 samples.

How the data were processed

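RNA from whole young flower buds of Arabidopsis thaliana, ecotype Columbia, was measured on 4 one-colour Agilent microarrays, each hybridised with the Cy3-labelled RNA of 1 sample. Per the labels, 2 samples were wild type and 2 were of the sdg2-1 mutant, the replicates were grown and harvested independently in a greenhouse with 16 h light and 8 h dark at 22 °C, and 2 µg of total RNA was labelled per sample. The scanner files hold spot intensities, which per the file headers were extracted with Agilent Feature Extraction 10.5.1.1 from 1 channel, with background subtraction and spatial and multiplicative detrending, and were not normalised between arrays. The deposited series table holds log2 values; its sorted values agreed within 0.00057 between arrays, so the authors' values carry a quantile normalisation, and its columns had a correlation of 0.986 to 1.000 with the log2 processed signal of their own array. The median of each of its columns was 9.37, and its values were not centred per gene. All 4 arrays lay on 1 slide and were read in 1 scan, so neither could be tested as a batch.

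The main values were log2 of the processed signal minus each array's 75th percentile of it. Control spots and spots with an outlier flag (23 to 48 per array) were left out, and spots of 1 probe were averaged. Of 43603 probes on 43803 spots, 37540 carried 1 locus identifier in the array's annotation, 873 carried several and 5190 carried none, and only the first kind entered the comparison of genes. A probe was kept when it was well above background on both arrays of at least 1 group, which left 34708 probes. Each gene was represented by its probe with the highest mean signal, which gave 22777 genes, of which 9398 had a symbol in the gene lists, the array's annotation or the reference gene table (assembly TAIR10.1, used for names only). Among 6241 genes with more than 1 kept probe, the probes of 1804 had differences of opposite sign. Coordinates are those of the probes in the array's annotation, whose build in the file headers is that of an older release than the reference table, and no exon or intron was assigned.

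Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The prior had 1.68 degrees of freedom. Differences are sdg2-1 minus wild type on the log2 scale, with the fit's standard error (SE). The 18 gene lists hold 258 loci, of which 239 were measured, and were tested against all other genes with camera at a preset correlation between genes of 0.01, with an estimated correlation and with fry beside it. Transposable element genes were taken from the array's descriptions. The groups, tests, lists, thresholds, most alternatives and the rule for named genes were fixed before the data were examined. The rule named SDG2 and the list of histone H3K4 methylation genes, the 12 genes with the widest change in each direction among those past the adjusted threshold, up to 4 members per list past that threshold or otherwise the 2 with the lowest p, and SPL, MS1, FLC and AG. Chosen after the values were seen were the list members past the adjustment over the list alone, AP3, PI and GRP17, and, because no gene passed the adjusted threshold, the 12 genes in each direction with the widest gap between the nearest arrays of the groups among genes well above background on all 4 arrays (for lower genes also above the dim level of wild type replicate 1).

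The number of arrays limits the precision. The fit was tested on simulated data: in 20 simulated sets of 22777 genes with the means and variance prior of the real comparison, 200 genes were changed. At a change of 1 on the log2 scale 68.3% had an unadjusted p below 0.05, at 2 this was 88.2% and at 4 it was 96.4%, while 0% of each size passed the adjusted threshold. A shift of -1 in the tapetum list was called by camera in 20 of the 20 sets at the preset correlation and in 0 of the 20 with an estimated correlation. The simulated genes were drawn independently of one another and without effects of single arrays. The sets therefore do not show how either setting behaves with correlated genes. Alternatives were normexp background correction (offset 50) on the mean spot and local background intensities, other scalings, no or a stricter filter, the mean of a gene's probes, the deposited log2 values, array weights, a mean-variance trend, the replicate number as a block, and leaving out each array. A filter that keeps genes whose mean lies above the dim level of wild type replicate 1 was added after the data were seen. That level is the 90th percentile, on that array, of probes not well above background on the other 3 arrays. Figures were drawn with matplotlib 3.10.9.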

Results

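Transcript levels were measured in whole young flower buds of wild-type Arabidopsis thaliana and of sdg2-1, a mutant of SDG2, which encodes a SET-domain protein of the histone H3 lysine 4 (H3K4) methyltransferase family. The comparison asks which transcripts differ between mutant and wild-type buds. Each group had 2 independently grown samples, and each sample had 1 array. The probes well above background were 96.2% on wild type replicate 1, 75.8% on wild type replicate 2, 81.0% on sdg2-1 replicate 1 and 80.9% on sdg2-1 replicate 2. The 25th percentile of the signal was 118 units on wild type replicate 1, against 30.4 on wild type replicate 2, 42.3 on sdg2-1 replicate 1 and 34.6 on sdg2-1 replicate 2, so dim probes were brighter on the first array. No spot was saturated.

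SDG2 (AT4G15180) was 53.3-fold lower in sdg2-1 buds. On the brighter of its 2 probes (chromosome 4, 8662365 to 8662424) the level was 0.25 ± 0.0086 (SD, n = 2) in wild type and -5.48 ± 0.19 (SD, n = 2) in the mutant, a log2 difference of -5.74 with an SE of 0.20. The other probe (chromosome 4, 8661780 to 8661839) was well above background on 1 of the 2 mutant arrays and was at least 32.6-fold lower, with the lowest signal well above background in place of the other. The adjusted p over all genes in limma was 0.160. It was 0.0420 with a mean-variance trend and 0.0475 with only genes above the dim level of wild type replicate 1. Where these probes lie relative to the insertion is not given in the labels. The other 16 members of the H3K4 methylation list had differences between -0.62 and 0.31, and none passed. Among them were the methyltransferases ATX1 to ATX5 and the demethylases JMJ14, LDL1 and FLD. ATX4 had -0.62 (SE 0.24; the smallest difference of its 3 probes was -0.067) and JMJ14 had -0.52 (SE 0.21). SDG2 was the 1 member lower when adjusted over the list alone, and the list did not stand apart from other genes (median -0.035, camera adjusted p = 0.787).

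Tapetum and pollen wall genes were lower in sdg2-1 buds. The tapetum is the anther's inner cell layer, which feeds the developing pollen and makes its wall. The list's 32 measured members had a median difference of -1.27, and the camera adjusted p was 1.02e-13. With an estimated correlation the adjusted p = 0.334, a setting under which a simulated shift of -1 was called in 0 of 20 sets of independent genes. By fry, which tests for a common direction, the adjusted p was 0.0106, but 0.565 without scaling, 0.119 with the replicate number as a block and 0.146 to 0.265 with 1 array left out. Over all genes 0 members passed in limma, with 24 lower at an unadjusted p below 0.05, and 24 were lower and 0 higher when adjusted over the list alone. This count of lower members was 8 without scaling, 0 without sdg2-1 replicate 1 and 17 to 20 with another array left out. The lipase EXL6 of the pollen coat differed by -3.90 (SE 0.50) and A9, a tapetum protein, by -2.22 (SE 0.23). The transcription factors of the tapetum DYT1, AMS, MYB80 and MS1 (AT5G22260) differed by -1.25 (SE 0.19), -1.02 (SE 0.22), -1.38 (SE 0.20) and -1.57 (SE 0.27). The sporopollenin enzymes MS2, CYP703A2 and CYP704B1 differed by -1.70 (SE 0.19), -1.70 (SE 0.21) and -1.56 (SE 0.18), and LAP5, LAP6 and ACOS5 by -1.26 (SE 0.26), -1.34 (SE 0.22; -0.68 on its other probe) and -1.28 (SE 0.21). GRP17, the pollen coat oleosin, differed by -0.12 (SE 0.35; 0.14 without scaling) and by 0.48 on its other probe. Dim probes were brighter on wild type replicate 1, where late pollen genes were also higher than on wild type replicate 2 by a median of 2.82 on the log2 scale. Without replicate 1 the list's median was -1.26 and its adjusted p 5.84e-12.

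**Figure D1:**
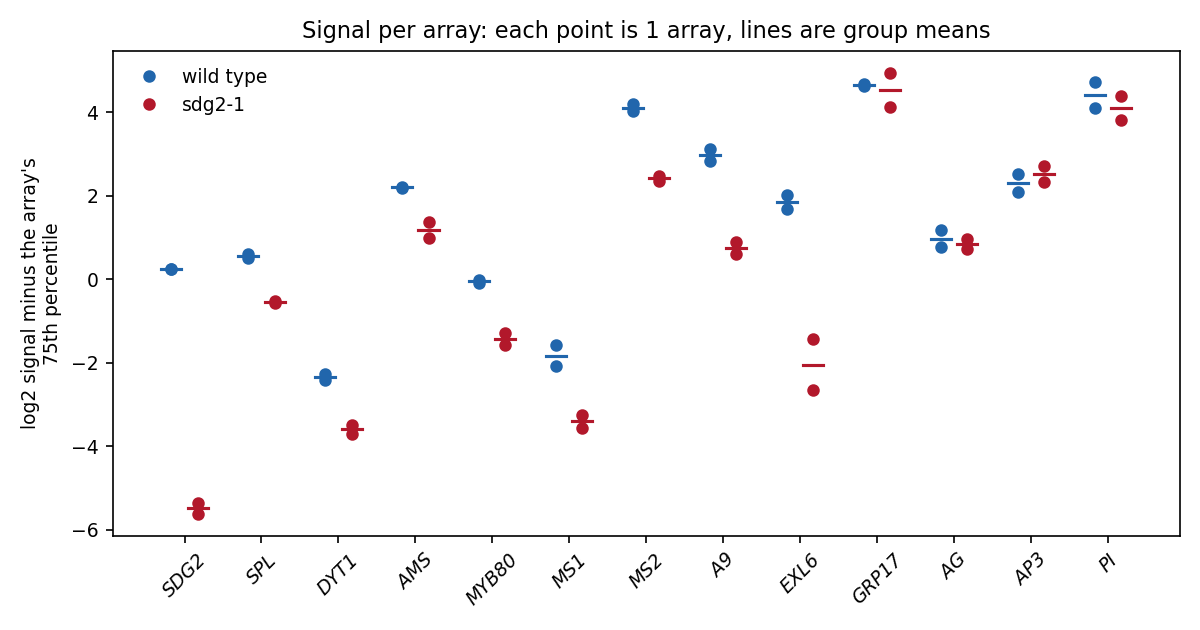
Log2 signal minus the array's 75th percentile (vertical axis) for SDG2, anther genes and floral organ identity genes (horizontal axis), with 1 point per array and a line at each group mean. SDG2 and EXL6 were lower by 5.74 and 3.90 on the log2 scale, whereas AG differed by -0.13 (0.13 without scaling), AP3 by 0.21 and PI by -0.31.

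Meiosis genes were lower by less. The median over 23 measured members was -0.36, with 0 members past the threshold over all genes and 0 when adjusted over the list alone (3 lower with normexp, 2 above the dim level). The camera adjusted p was 0.00576, and with an estimated correlation the adjusted p = 0.798. TDM1, which acts at the exit from meiosis, differed by -2.04 (SE 0.37), and ASY1, a protein of the chromosome axis, by -1.66 (SE 0.30). With quantile normalisation the median was -0.13 (adjusted p 0.221), without wild type replicate 2 the adjusted p was 0.389, and without sdg2-1 replicate 1 it was 0.0533. SPL (SPOROCYTELESS, AT4G27330), which is required for sporocyte formation, was 0.52 and 0.60 on the wild-type arrays and -0.56 and -0.52 on the mutant arrays, a difference of -1.09 (SE 0.17) with an adjusted p of 0.177 in limma. The glutaredoxin ROXY2 of early anthers differed by -1.77 (SE 0.41). The early anther and sporocyte list of 12 measured genes, to which both belong, had a median of -0.27 and a camera adjusted p of 0.353, and 0 members passed when adjusted over the list alone.

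Late pollen and sperm genes had a median difference of -1.45 over 25 measured members (camera adjusted p 0.0137; with an estimated correlation the adjusted p = 0.913). ACT12, a pollen actin, was the 1 member lower when adjusted over the list alone, at -2.21 (SE 0.20). There were 0 such members with quantile normalisation, with the deposited values and without scaling. AGL104, a transcription factor of pollen, differed by -1.58 (SE 0.43). Its wild-type levels, -5.20 and -5.83, lay below the dim level of wild type replicate 1 (-4.78). The list's median level was -2.54 on wild type replicate 1 and -5.66 on wild type replicate 2, against -5.07 and -6.32 on the mutant arrays, and 18 of the members were over 2-fold higher on the first wild-type array than on the second. Without wild type replicate 1 the median was -0.039 and the adjusted p 0.724. Without sdg2-1 replicate 2 they were -0.72 and 0.0991, and with only genes above the dim level -0.74 and 0.117. The call was lost in each of these 3 settings.

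**Figure D2:**
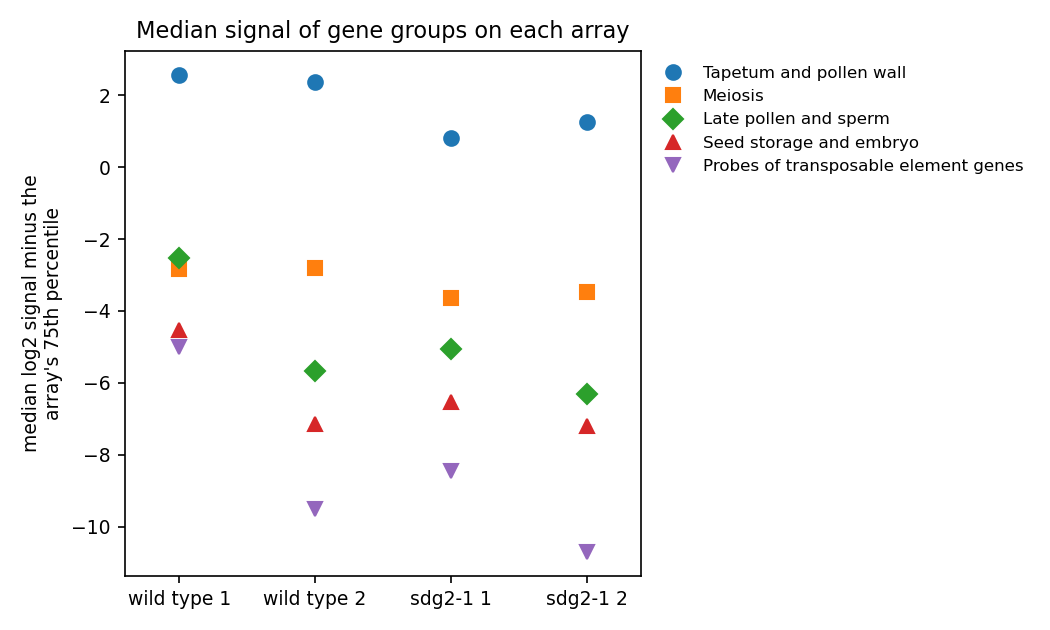
Median log2 signal minus the array's 75th percentile (vertical axis) of 4 gene lists and of the probes of transposable element genes on each of the 4 arrays (horizontal axis). The tapetum list lies at 2.58 and 2.37 in wild type and at 0.83 and 1.27 in sdg2-1, whereas the late pollen list lies at -2.54 on wild type replicate 1 and at or below -5.07 on the other arrays.

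The other lists did not pass the camera test. AG, AP3 and PI, which specify the reproductive organs and petals, differed by -0.13 (SE 0.24; 0.13 without scaling and 0.26 on its other probe), 0.21 (SE 0.28) and -0.31 (SE 0.35), SEP4 by 0.80 (SE 0.27) and CAL by 0.44 (SE 0.19). The floral organ identity list had a median of -0.014 over 12 genes (adjusted p 0.511; -0.15 to 0.30 with 1 array left out). FLC, a repressor of flowering, differed by -0.58 (SE 0.29), MAF4 by -0.78 (SE 0.30) and FT by -0.48 (SE 0.19), and the flowering time list had a median of -0.10 over 11 genes (adjusted p 0.787). STK and SHP2, which act in ovules and carpels, differed by -0.95 (SE 0.31) and -0.87 (SE 0.24), and their list had a median of -0.22 over 14 genes (adjusted p 0.304). The Polycomb list had a median of 0.058 over 8 genes (adjusted p 0.787), with EMF1 at -0.42 (SE 0.22) and SWN at -0.15 (SE 0.22). The jasmonate and stamen maturation list had 0.049 over 9 genes (adjusted p 0.406), with AOS at 0.77 (SE 0.26) and JAZ1 at 0.72 (SE 0.31). The salicylate and defence list had 0.47 over 9 genes (adjusted p 0.237), with NPR1 at 0.47 (SE 0.20) and PR5 at -0.98 (SE 0.42), where its other probe had 1.52. Without sdg2-1 replicate 2 this list passed (median 0.47, adjusted p 0.0262; adjusted p = 0.889 with an estimated correlation), and without sdg2-1 replicate 1 its median was -0.12. The photosynthesis list had -0.17 over 16 genes (adjusted p 0.658), with RBCS2B at 0.71 (SE 0.21) and LHCA2 at -0.29 (SE 0.18). The cell cycle list had 0.087 over 12 genes (adjusted p 0.473), with CYCA2;1 at -0.49 (SE 0.18) and CDKB2;2 at 0.57 (SE 0.32). The meristem and boundary list had 0.16 over 9 genes (adjusted p 0.511), with CUC3 at 0.57 (SE 0.30) and KNAT2 at 0.51 (SE 0.30). The seed storage and embryo list had -1.02 over 8 genes (adjusted p 0.304), with CRA1 at -1.10 (SE 0.75; -4.07 on its other probe), and SESA1, not well above background on either mutant array, at least 3.16-fold lower. That bound sets the wild-type mean against the mean of the lowest signal well above background, or the probe's own if higher, on the mutant arrays, and the adjusted p in limma was 0.235. The wild-type levels of SESA1, -6.16 and -7.06, lay below the dim level of wild type replicate 1 (-4.78). The bound may thus rest in part on the raised dim signal of that array. Without wild type replicate 2 the list passed (median -2.52, adjusted p 0.000486; adjusted p = 0.912 with an estimated correlation), and without wild type replicate 1 its median was 0.42. The clock list had -0.35 over 10 genes (adjusted p 0.905), with TOC1 at -1.22 (SE 0.61) and GI at -1.03 (SE 0.54). TOC1 was at -0.033 and 0.70 in wild type, -0.18 in sdg2-1 replicate 1 and -1.59 in replicate 2, and GI at 1.02 and 0.76, 0.54 and -0.81, so that both differences rest largely on sdg2-1 replicate 2. Of the silenced loci, 1 was measured, SDC, at -1.19 (SE 0.71; 0.20 with quantile normalisation), with a list adjusted p of 0.511.

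**Figure D3:**
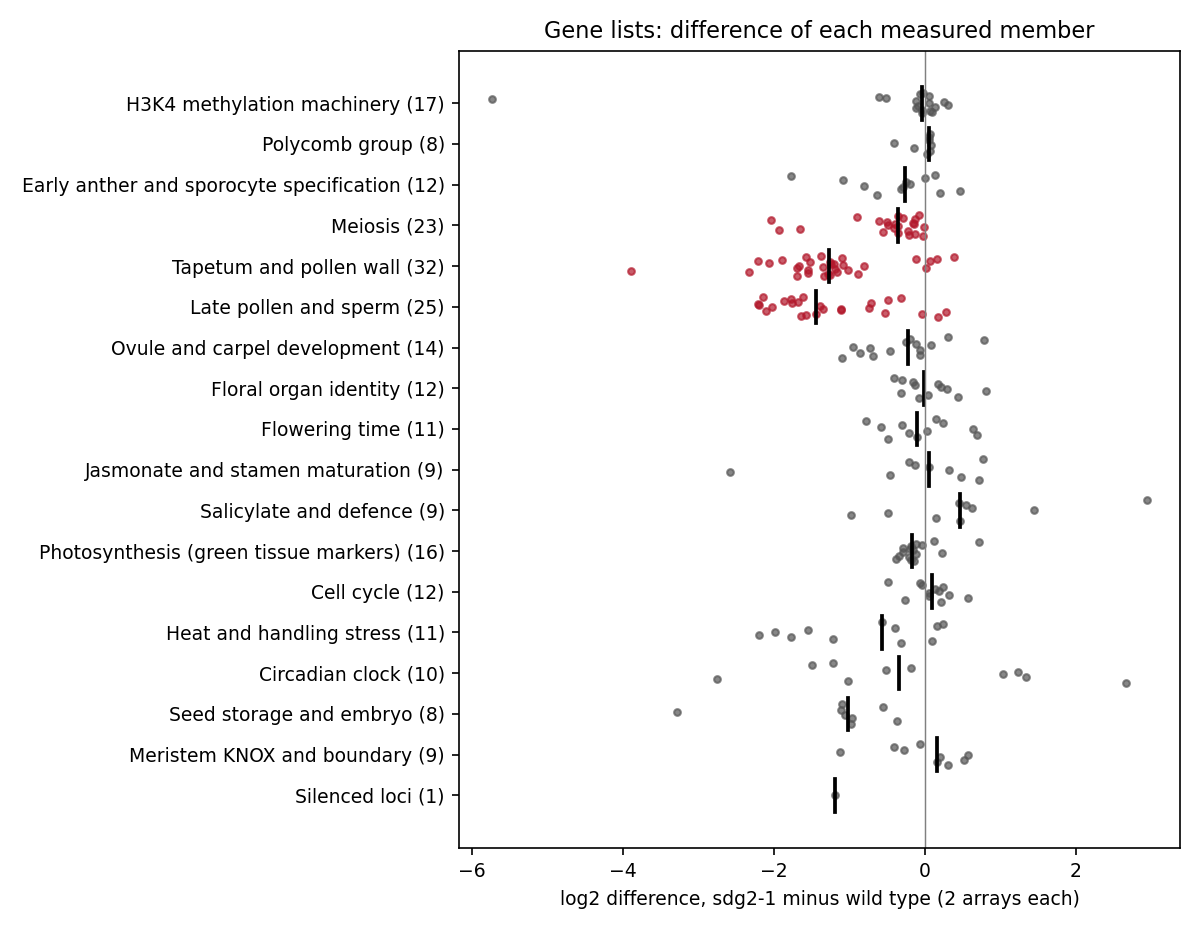
Log2 difference of each measured gene (horizontal axis, sdg2-1 minus wild type) in the 18 lists (vertical axis, number measured in brackets), with a black bar at each list's median. Red points mark the lists with a camera adjusted p below 0.05: tapetum and pollen wall (median -1.27), meiosis (-0.36) and late pollen and sperm (-1.45). None passed with an estimated correlation (adjusted p = 0.334, 0.798 and 0.913 with an estimated correlation).

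Heat and handling stress genes had a median of -0.57 over 11 genes and a camera adjusted p of 0.0923. CBF2, a transcription factor of the cold response, was lower when adjusted over the list alone, at -2.20 (SE 0.29), and CBF1 differed by -1.55 (SE 0.36). No member, 0 in each case, was lower over the list alone with quantile normalisation, the deposited values, no scaling or no filter. Without wild type replicate 1 the list's median was -1.28 and its adjusted p 0.000238 (adjusted p = 0.922 with an estimated correlation), and without sdg2-1 replicate 2 they were -0.71 and 0.0262 (adjusted p = 0.889 with an estimated correlation). Without sdg2-1 replicate 1 they were -0.41 and 0.177, and without wild type replicate 2 they were -0.18 and 0.833. Transposable element genes, as the array's annotation describes them, had a median of -0.79 over 238 measured genes (camera p 0.000344; with an estimated correlation the p = 0.576), and 0 passed the adjusted threshold in limma, with 4 higher and 36 lower at an unadjusted p below 0.05. Without wild type replicate 1 the median turned to 0.31 (camera p 0.0730), so that the lower level in sdg2-1 rests on that array.

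Over all 22777 genes, 0 passed the adjusted threshold in limma, and the smallest adjusted p was 0.160. At an unadjusted p below 0.05 there were 644 higher and 2225 lower genes, where 1139 in all would be called by chance. The split depends on the scaling: it was 1108 higher and 1507 lower with quantile normalisation, 1103 and 1505 with the deposited values, and 963 and 1673 without scaling. Without wild type replicate 1 it was 1331 and 2005. Genes at least 2-fold apart between every mutant and every wild-type array numbered 113 higher and 1297 lower (603 lower with quantile normalisation, 621 among genes above the dim level). With a mean-variance trend 4 genes passed, all lower: SDG2, MRD1, AT5G16920 and AT1G23560. The latter pair, with differences of -3.39 and -3.73, was named after the values were seen. In simulations of this comparison with 200 changed genes, none of these passed the adjusted threshold either, so the count of 0 does not show that no gene differs. Sets with more changed genes were not simulated, although 2869 genes in all had an unadjusted p below 0.05 in the data.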

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

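Among probes that the array's annotation assigns to no locus, and which therefore entered no comparison of genes, 20 were well above background on both sdg2-1 arrays and on neither wild-type array. They were picked out as signal outside the main measurement that the scanner software did not call well above background in the control samples. The opposite pattern, well above background on both wild-type arrays and neither sdg2-1 array, was equally frequent, with 20 of the 5172 probes looked at. These are the probes without a locus, 5190 in all, that had a value on every array. For probes of the first kind only a lower bound on the difference from wild type can be given. It ranged from 0.907-fold, which shows no difference, to 1.54-fold. The probe with the largest bound was at -5.44 and -8.18 on sdg2-1 replicates 1 and 2. There the lowest signals well above background were -7.77 and -8.76.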

How the results depend on the processing

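The mean-variance trend for SDG2, the filter on the dim level of wild type replicate 1 and the count of genes at least 2-fold apart in every array pair were chosen after seeing the data. The lower level of SDG2 (-4.96 with normexp, where the difference was smallest) and the lower median of the tapetum list kept their direction under every alternative run, with SDG2 between -5.87 and -5.60 and the tapetum list between -1.42 and -1.14 when 1 array was left out. By camera at its preset correlation the tapetum list also kept its side of the threshold under every alternative. It lost it with an estimated correlation, and its call by fry (adjusted p 0.0106) was lost without scaling (0.565), with the block (0.119) and whenever 1 array was left out (0.146 to 0.265). In all, 131 summary values and 1489 values of single genes and uncalled lists were labelled unchanged. For counts this meant a value near that of the main analysis, and otherwise the same direction and side of the threshold. Of the remaining summary values, 29 were labelled moved, 13 weaker (no longer past the threshold), 2 stronger and 1 reversed. Among single genes and uncalled lists, 61 values were reversed. As 0 genes passed in the main analysis and few under any alternative, the side of the threshold says little for single genes. Further, 7 values of uncalled lists passed the threshold under an alternative, none with an estimated correlation. They were heat and handling stress without scaling, with the block, without wild type replicate 1 and without sdg2-1 replicate 2, seed storage without scaling and without wild type replicate 2 (adjusted p 0.000486), and salicylate and defence without sdg2-1 replicate 2 (adjusted p 0.0262). With 1 array left out, the lone array of a group is assumed to vary like the other group. The cause of the changes below was not tested unless stated. Not run were slide and scan as a block, as there was 1 of each, and leaving out saturated probes, as none was saturated. Signal over background limits what can be read from dim genes on wild type replicate 1.

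In limma, 0 genes passed the adjusted threshold in the main analysis, 0 under every alternative but 2, 4 genes with a mean-variance trend and 1 gene, SDG2, with only genes above the dim level, where fewer genes were tested. The difference of SDG2 was then -5.74 in both, with adjusted p of 0.0420 and 0.0475, where its alternatives ranged from 0.0420 to 0.604. Genes higher at an unadjusted p below 0.05 numbered 644, and 1108 with quantile normalisation, 1103 with the deposited values, 391 with no filter and 1172 when probes were counted. Leaving out 1 array gave 217 to 1331 higher and 1418 to 3949 lower genes. Genes at least 2-fold apart in every array pair numbered 113 higher and 1297 lower. There were 297 and 603 with quantile normalisation, 297 and 610 with the deposited values, 224 and 858 without scaling, 728 lower with normexp, 621 lower above the dim level and 200 higher when probes were counted. Leaving out 1 array, which leaves fewer pairs, gave 245 to 1018 higher and 1723 to 3577 lower genes. The 2 other ways to split the arrays gave 594 and 42 genes (replicate 1 against replicate 2) and 32 and 12 genes (crossed), and splits this few cannot give a share under 0.05.

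Replicate numbers are shared between the groups, and same-numbered arrays deviated together (correlation 0.426 over kept probes, 0.415 above the dim level). Above that level, wild-type replicates correlated at 0.952 and sdg2-1 replicates at 0.968. Same-numbered arrays of the 2 groups correlated at 0.954 (replicate 1) and 0.952 (replicate 2), and differently numbered ones at 0.929 and 0.943. The labels name no shared harvest, so what same-numbered arrays have in common is not known. With 2 pairs, the number was used as a block only as an alternative. With the replicate number as a block, 0 genes passed, 4 lists were called in place of 3, and the added call was heat and handling stress at a median of -0.57 (adjusted p 0.0366; adjusted p = 0.895 with an estimated correlation).

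The value given for a list is its median, and its direction is that of camera, so a list near 0 can turn with its median unmoved. Of the 3 lists called, 0 were called with an estimated correlation (medians -1.27, -0.36 and -1.45) and 1 with fry, the tapetum list. Without scaling 5 were called, with the addition of heat and handling stress (-0.31) and seed storage (-0.77), both with an adjusted p = 0.867 with an estimated correlation. Meiosis lost its call with quantile normalisation and with the deposited values (both -0.13), and when 1 array was left out ranged from -0.41 to -0.26. Late pollen lost its call above the dim level (-0.74) and ranged from -2.96 to -0.039. The transposable element genes lost theirs with an estimated correlation (-0.79) and ranged from -2.11 to 0.31, reversed at 0.31 without wild type replicate 1. Compared with the main analysis, the median of all genes moved by 0.26 without scaling and by -0.13 with no filter, which accounts for turns of values near 0.

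Apart from the transposable element genes, the values that turned direction were of lists and genes that passed no test over all genes. Without scaling these were flowering time (0.15), the H3K4 list (0.22), photosynthesis (0.083), AG (0.13), ATX2 (0.22), ATX3 (0.14), ATX5 (0.23), ATXR7 (0.19), FLD (0.16), GRP17 (0.14), SDG26 (0.21), SDG8 (0.13) and SWN (0.11). With quantile normalisation they were photosynthesis (0.016), Polycomb (0.064), FLD (0.035) and SDC (0.20), and with the deposited values photosynthesis (0.012), Polycomb (0.064), FLD (0.035) and SDC (0.20). With the mean of a gene's probes they were photosynthesis (0.085), AG (0.067), ATX1 (-0.17), GRP17 (0.18) and PR5 (0.27). With no filter they were the clock (-0.35), flowering time (-0.10) and H3K4 (-0.035) lists, and with the block flowering time (-0.10). Leaving out 1 array gave ranges of -1.01 to -0.098 for the clock list, -0.30 to -0.095 for flowering time, -0.16 to 0.061 for the H3K4 list, -1.28 to -0.18 for heat and handling stress, -0.42 to 0.58 for jasmonate, -0.17 to 0.48 for meristem and boundary, -0.40 to 0.045 for photosynthesis, -0.033 to 0.083 for Polycomb and -2.52 to 0.42 for seed storage. Medians alone turned, with camera's direction kept, for floral organ identity (-0.15 to 0.30; 0.10 with quantile normalisation) and salicylate and defence (-0.12 to 0.58), and for ovule and carpel without scaling (0.032) and jasmonate with no filter (-0.17). Over the list alone, the alternatives with all 4 arrays gave 0 to 5 lower members for late pollen and 0 to 3 for meiosis and for heat and handling stress. They gave 0 to 1 for the early anther, seed storage and silenced loci lists. For genes the ranges were AG -0.32 to 0.072, AP3 -0.0084 to 0.44, ATX1 -0.11 to 0.38, ATX2 -0.31 to 0.24, ATX3 -0.24 to 0.010, ATX5 -0.17 to 0.12, FLD -0.33 to 0.14, GRP17 -0.53 to 0.29, PI -0.62 to 0.0054, RBL -0.016 to 0.12, SDG26 -0.39 to 0.30, SDG4 -0.27 to 0.36, SDG8 -0.29 to 0.050 and SWN -0.33 to 0.038.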

Other observations

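All tests of explanations in this part were chosen after the result was seen, as were the genes with the widest gap between the groups' nearest arrays.

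Outside the lists, several genes lay far apart between the groups. None passed the adjusted threshold in limma (smallest adjusted p 0.160). Lower in sdg2-1 on both arrays were MRD1, at 0.64 ± 0.52 (SD, n = 2) in wild type and -4.90 ± 0.10 (SD, n = 2) in the mutant, a difference of -5.54 (SE 0.33), and SAG12, a cysteine protease of senescence, at -3.85 (SE 0.46). The jacalin lectin JAL34 differed by -2.84 (SE 0.19), the glycoside hydrolase gene AT1G56680 by -3.35 (SE 0.30), the cellulase family gene AT3G26140 by -3.96 (SE 0.52) and the pectin methylesterase inhibitor gene AT5G50060 by -3.16 (SE 0.21). The actin-binding LIM protein gene PLIM2c differed by -3.35 (SE 0.38), the microRNA gene MIR856 by -3.94 (SE 0.61), the noncoding RNA gene AT4G13495 by -3.47 (SE 0.32) and the myrosinase-associated pseudogene AT1G18120 by -3.43 (SE 0.29).

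Higher in sdg2-1 on both arrays were MLP43, at -1.95 ± 0.39 (SD, n = 2) in wild type and 1.19 ± 0.19 (SD, n = 2) in the mutant, a difference of 3.15 (SE 0.28), and RLM3, a gene of the TIR disease resistance class, at 2.68 (SE 0.27). The dirigent family gene AT4G11210 differed by 4.03 (SE 0.82), the esterase gene MES1 by 3.58 (SE 0.67), the defensin-like gene AT2G16367 by 3.42 (SE 0.75) and AT3G26470, similar to the resistance gene ADR1-L1, by 3.14 (SE 0.68). DRNL, a transcription factor of organ primordia, differed by 2.88 (SE 0.54), BZIP24 by 2.30 (SE 0.28), DOT1 by 3.30 (SE 0.88) and the RNA gene AT3G29644 by 2.11 (SE 0.22; 0.69 on its other probe). For 2 further genes the second probe did not show the difference: the glycine-rich protein gene AT1G04660 had 2.81 (SE 0.35) on one probe and -0.62 on the other, and the acetyltransferase gene AT3G22560 had 2.12 (SE 0.22) and 0.21. On both wild-type arrays DRNL, BZIP24, DOT1 and MES1 lay below the dim level of wild type replicate 1 (-4.78). AT4G11210, AT2G16367, AT3G26470 and AT3G22560 did so on wild type replicate 2. The sizes of these differences are therefore uncertain. DOT1 was at -3.06 and -0.77 on the mutant arrays.

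The first pattern weighed is the lower level of tapetum and pollen wall genes in sdg2-1. The raised dim signal of wild type replicate 1 is argued against, because the list's median without that array was -1.26. A lower share of petals and stamens together is argued against by AP3 and PI, whose mean difference was -0.047, above the list's median of -1.27. The SE of that mean, 0.22, treats the 2 genes as independent. Both were lower on replicate 2 than on replicate 1 in each group, so it may be too small. Each gene alone, AP3 at 0.21 (SE 0.28) and PI at -0.31 (SE 0.35), also lay above the list's median. Buds of an earlier stage in sdg2-1 cannot be told apart from an effect of the genotype, since the early anther and sporocyte list had a camera p of 0.157 and so decided nothing. That sdg2-1 anthers may hold less tapetum transcript at a given stage stays a hypothesis, beside SPL at -1.09 and DYT1, an early tapetum regulator, at -1.25.

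The second pattern is the brighter signal of dim probes, transposable element genes and late pollen genes on wild type replicate 1. Probes not well above background on the other 3 arrays had a median signal of 56.8 units there, against 5.97, 5.19 and 2.90 on wild type replicate 2 and sdg2-1 replicates 1 and 2, but its negative control spots had a median of 4.91 against 5.70, 4.43 and 2.66, which argues against background light shared by all spots. On wild type replicate 1, 16 of 25 late pollen members exceeded their replicate 2 level plus the dim level (the 90th percentile of dim probes). From other genes of the same level on replicate 2, 8.26 were expected (97.0% range 4 to 13). That range takes members as independent, but the list's estimated correlation was 0.456, so it may be too narrow. The median ratio over the 25 members was 2.30, and its 95.7% interval, 0.938 to 3.25, includes 1. These values therefore cannot decide whether the dim signal alone is the source for the late pollen genes. The lower level of transposable element genes in sdg2-1 may come from wild type replicate 1, because their median without it was 0.31. Older buds or open flowers in that sample, which were not tested, remain a candidate source of the pollen transcripts. The seed storage and embryo list was also higher there than on wild type replicate 2, by a median of 2.25. Of its members, 7 of 8 were over 2-fold higher. The list's median level there was -4.52, near the dim level of -4.78, and 0 members had a mean over the arrays above that level. Its rise may thus come from the raised dim signal and cannot speak for or against older buds.

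The third pattern is the clock genes of sdg2-1 replicate 2. The morning gene LHY was at 0.32 on that array and at -4.37, -6.15 and -5.52 on wild type replicates 1 and 2 and sdg2-1 replicate 1, and the evening gene ELF4 was at -4.17 against 1.72, 1.60 and 1.99. An effect of the genotype is argued against, because the mean of 4 morning genes minus that of 5 evening genes in sdg2-1 replicate 1 differed from the wild-type mean by -0.42, less than the 1.74 between the wild-type replicates, while replicate 2 differed by 6.36. Another time of harvest cannot be told apart from another disturbance of the clock in that sample. Its direction was that of 9 of the 9 genes, morning genes higher and evening genes lower than on the other 3 arrays, with PRR7, given no phase, at -0.29, but these genes regulate one another and the labels give no time of harvest.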
